A study of Mus musculus with 17 samples.

How the data were processed

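The samples were whole mammary glands of nulliparous female C57Bl/6 mice of 4 genotypes, in 17 libraries. Per the labels' protocols, polyadenylated RNA was made into cDNA libraries with a TruSeq kit and sequenced on an Illumina HiSeq instrument by single- and paired-end methods. Per the submitters' processing notes, FastQC, Trim Galore, TopHat and Cufflinks were used with the mouse build mm9; their versions are not given in the sources used here. TopHat aligns spliced reads and Cufflinks assembles transcripts and estimates FPKM, which scales fragments by transcript length and by the total of mapped fragments.

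The authors deposited 1 table of FPKM values with 30843 loci and 8 columns, 1 for each genotype and read layout by their names. The 4 columns labelled single-end were used, 1 per genotype, and the labels give 2 single-end libraries for every genotype. The other 4 columns are those of the paired-end libraries (1 of WT, 3 of AROM, 3 of CERM and 2 of BRCA). They were not used for the values given here. This choice, the filter over 4 columns and the rule for calls were made after both layouts had been compared. In that comparison, of which no value is given here, most genes past 2-fold between AROM or CERM and WT in the single-end columns were not past 2-fold in the paired-end ones, and those past it in both layouts were mostly lower in AROM. Against WT, muscle genes were higher by less in the paired-end columns of AROM and CERM, and macrophage and matrix genes higher by more in that of CERM. The differences described below are those of the columns labelled single-end and are given without the paired-end values.

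How the libraries were combined is not given in the sources used here. In the WT column 46.7% of the values carry repeating decimals, as a mean of 3 values would, although the labels give 2 single-end WT libraries, and in the other 3 columns this share was at most 0.0195%. The labels hold 3 WT libraries in all, 2 single-end and 1 paired-end, so the WT column may pool both layouts; which 3 values were averaged was not settled. Every comparison with WT carries this limit. The columns carry no counts. Ratios of low values between columns did not give whole reads, so the depth of each library and the counting error of each value are unknown. FPKM summed over all loci came to 960589 in the WT column, and unnamed loci took between 42.9% and 48.9% of the sum in the 4 columns. Sums were therefore not used for scaling, and values were compared as deposited.

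Of the 30843 loci, 8119 had no gene name, 585 had several gene symbols and 1719 shared a symbol with another locus. The remaining 20420 loci had 1 symbol of their own, and the 11715 of them with FPKM of at least 1 in at least 2 of the 4 columns were analysed. Of these symbols, 11639 were found in the GENCODE M21 or RefSeq tables. Those tables are of a later mouse build than the files use, so they served for names and for the order of neighbouring genes, and no coordinates are given. Genes with near-identical copies (pseudogenes, the serpin and Trim12 families) may share reads, and the strand handling of the authors' quantification is not given in the sources used here, so overlapping genes could not be separated.

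For each pair of genotypes the log2 ratio of FPKM + 1 was computed; this scale understates the ratio of low genes. A gene was called higher or lower when it was at least 2-fold apart. The tests planned before the data were examined, limma fits over the 17 libraries with camera tests of gene lists, could not be run because the table has no column for each library. The FPKM minimum, the pseudocount, the 6 comparisons and 33 gene lists of cell types and pathways were set before the data were examined. Lists were summarised by the number of members past 2-fold and by the median log2 fold change, with its percentile among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression. The percentile describes these columns and is not a test, and lists with fewer than 3 genes analysed got none.

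The genes named in the report were chosen by rule. They are Esr1, Cyp19a1, Brca1, Trp53 and Pgr; the 8 highest and 8 lowest genes past 2-fold of each of the 4 main comparisons (5 and 5 in the 2 further ones), ranked by fold change; and up to 4 members of each list described, ranked the same way. Genes listed at 0 in a column compared were left out of the ranking. Names without a known identity, such as those with Gm, Rik, Mir or Snor, were counted but not ranked. Outside this rule, Ncl was added after its values were seen, as were the genes named first in the closing observations. A few results on single genes are not reported here.

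The rule was tested on simulated data: 11715 genes at their real mean values, with noise resampled from the real deviations of the 4 columns from each gene's mean. For a simulated pair of genotypes it recovered 89 of 100 genes set 4-fold apart and 36 of 100 set 2-fold apart, and called 537 of 11515 genes set equal. Of 50 simulated lists of 10 genes set 2-fold apart, 50 passed the 97.5th percentile, and 9 of 200 lists of equal genes passed the 2.5th or 97.5th. The noise includes the real differences between genotypes, so these figures give no error rate. It was also drawn for each gene separately, while the genes of a real list may vary together. How often such a list reaches an extreme percentile was not simulated. Other pseudocounts (0.1 and 0.5), filters, scalings (quantile and median-ratio) and fold thresholds were tried as alternatives. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.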

Results

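Polyadenylated RNA from whole mammary glands of nulliparous female C57Bl/6 mice was sequenced in 4 genotypes. AROM mice carried a tetracycline-controlled CYP19A1 transgene, the gene of aromatase, which makes estrogens from androgens. CERM mice carried an Esr1 transgene, the gene of estrogen receptor alpha, under the same control. BRCA mice lacked exon 11 of the DNA repair gene Brca1 in MMTV-Cre-expressing cells and had 1 functional Trp53 allele, and the wild-type (WT) mice carried none of these changes. The labels list 17 libraries, 8 of them single-end, with 2 single-end libraries for each genotype. The values analysed were 4 pooled columns, the authors' FPKM value per gene for each genotype in the columns labelled single-end. The WT column carries decimals as of means of 3 values, and the labels hold 3 WT libraries, 1 of them paired-end, so every comparison with WT may set a mixed column against single-end ones. With 1 value per gene and genotype there was no spread between replicates, no p-value was computed, and no difference below has a replicate check. The paired-end columns were looked at before these were chosen, and their values are not given. Most genes past 2-fold between AROM or CERM and WT in the columns used were not past 2-fold there. The sequencing depth behind each column is unknown. Median FPKM over the 11715 genes analysed lay between 9.24 and 9.87 in the 4 columns. A value of 0 in such a table can be a failed estimate. Ncl, the nucleolin gene that every cell needs, was listed at 0 in WT and at 102 FPKM in AROM, and 47 of the genes analysed were listed at 0 in at least 1 column.

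The engineered genes were compared first, as a check on the labels. Esr1 was at 8.49 FPKM in CERM, 7.27 in WT, 8.41 in AROM and 6.59 in BRCA, so CERM was 1.17 times WT and 1.01 times AROM. This value does not set CERM apart from AROM and shows no clear over-expression of Esr1, so CERM is a name taken from the label. Mouse Cyp19a1 was at 0.0591 FPKM in AROM and listed at 0 in the other columns, and the transgene is the human gene, so this locus is no measure of it. Trp53 was at 12.3 FPKM in BRCA and 41.1 in WT, a ratio of 0.2995, with 29.5 in AROM and 28.0 in CERM. Brca1 was at 3.28 FPKM in BRCA and 1.13 in WT, 2.90 times WT, with 0.881 in AROM and 0.661 in CERM. A value over the whole locus does not measure exon 11, so the higher Brca1 value does not check the knockout label. Trp53 was lowest in BRCA, the direction of 1 functional allele, but it was below WT in AROM and CERM too. The label was not settled by these values, so this is called the column labelled BRCA below. Pgr, the progesterone receptor gene and a target of estrogen receptor, was at 1.92 FPKM in WT, 1.497 in AROM, 1.14 in CERM and 0.654 in the column labelled BRCA.

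**Figure D1:**
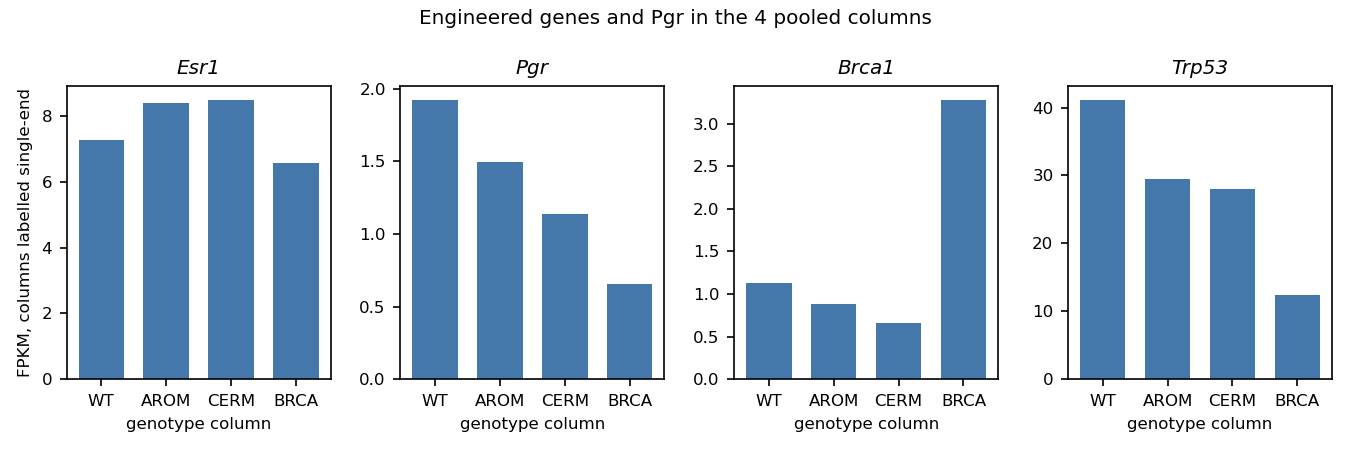
FPKM (y axis, from 0) of Esr1, Pgr, Brca1 and Trp53 in the 4 genotypes (x axis); each bar is the authors' value in the column labelled single-end, with no error bar because each column holds 1 value per gene. Brca1 stands at 3.28 FPKM in the column labelled BRCA against 1.13 in WT, and Trp53 at 12.3 against 41.1.

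The comparison of AROM with WT asked which genes differ in mice labelled as carrying the aromatase transgene, whose expression was not measured here. Milk genes were far lower in AROM. Glycam1, which encodes a secreted mucin-like glycoprotein, was at 4.99 FPKM against 518 in WT, and Wap, the whey acidic protein gene, at 3.95 FPKM against 143. The casein genes followed, with Csn1s2a at 554 FPKM against 5103 and Csn2 at 764 FPKM against 6520.2. Glycam1 is also in the lymph node stroma list, of which 2 of 3 genes analysed, Glycam1 and Madcam1, were lower, with a median of -2.01. Of the 13 milk genes analysed, 10 were at least 2-fold lower and none was 2-fold higher, and the median log2 fold change of the list was -1.88. Luminal epithelial genes were also lower, 7 of 13 by 2-fold or more, with a median of -1.04. Among them were the adhesion gene Cdh1 (22.6 FPKM against 55.4), the tight junction gene Cldn7 (16.2 FPKM against 38.3) and the epithelial transcription factor gene Ehf (21.3 FPKM against 49.4). Of the 6 luminal progenitor genes 2 were lower, Elf5, which directs alveolar differentiation (39.0 FPKM against 108), and Cd14 (38.1 FPKM against 80.1). None of the 9 basal and myoepithelial genes passed 2-fold, and their median was -0.28.

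Further low ratios in AROM were those of Gjb6, a gap junction connexin gene (2.48 FPKM against 40.8), and Pigr, whose product carries immunoglobulin A across epithelia (1.24 FPKM against 21.5). Madcam1, which encodes the vascular addressin of mucosal lymphoid tissue, was at 1.77 FPKM against 10.2. Tnfsf11, encoding the RANK ligand that relays progesterone signals, was at 4.83 FPKM against 15.4 and was the only one of 8 hormone-sensing luminal genes past 2-fold. In the estrogen response list 2 of 11 genes were 2-fold lower, Tnfsf11 and Myc (19.1 FPKM against 41.9), none was 2-fold higher, and the median was -0.27. None of the 24 proliferation genes passed 2-fold, and their median was -0.34, with Birc5 at 5.02 FPKM against 10.8. Of the 10 T cell genes Cd3g was lower (2.73 FPKM against 6.78), and the list median was -0.42.

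Skeletal muscle genes were higher in AROM, 11 of 11 by 2-fold or more, with a median of 1.57. The fast myosin heavy chain gene Myh4 was at 1304 FPKM against 387, the troponin gene Tnnc2 at 5333 FPKM against 1646, and Pgam2, the muscle phosphoglycerate mutase gene, at 808 FPKM against 233. The Schwann cell gene Prx was at 7.65 FPKM against 3.28. Ifi27l2a, an interferon-inducible gene, was at 2555 FPKM against 609. Among interferon-stimulated genes 1 of 17, Xaf1, passed 2-fold (11.7 FPKM against 2.89), and the list median was 0.24. Prtn3, a neutrophil protease gene, was at 13.1 FPKM against 2.46, the mast cell tryptase gene Tpsb2 at 29.1 FPKM against 13.6, and Ido1 at 1.61 FPKM against 0.0740. White adipocyte genes had a median of 0.29, with 1 of 12, the adipsin gene Cfd, past 2-fold (5198 FPKM against 1947). Of the 6 brown adipocyte genes Elovl3 was higher (13.3 FPKM against 5.39), and of the 15 fibroblast and matrix genes Thbs2 (19.2 FPKM against 8.07). Hmga2-ps1, a pseudogene that may share reads with its parent gene, was at 10.5 FPKM against 2.25.

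Several widely expressed genes also stood among the most distant. Higher in AROM were the kinase gene Irak1 (217 FPKM against 22.9), Chpf2 (58.1 FPKM against 10.4), Prmt2 (232 FPKM against 49.2) and the DNA repair gene Ercc2 (165 FPKM against 40.3). Lower were Tsr1, a ribosome maturation gene (9.80 FPKM against 592), and Hipk3 (24.3 FPKM against 149). With Ncl listed at 0 in WT, such isolated values are of uncertain meaning.

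In all, 280 genes were at least 2-fold higher and 199 at least 2-fold lower in AROM than in WT, out of 11715. The higher genes made up 58.5% of these, but 41.3% of the 63 genes past 4-fold. The milk, luminal epithelial, luminal progenitor, proliferation and lymph node stroma medians stood below every one of 10000 random lists of matched expression (0th percentile), and the muscle median above every one (100th percentile). Muscle genes were higher by less in the paired-end columns, whose values are not given here.

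**Figure D2:**
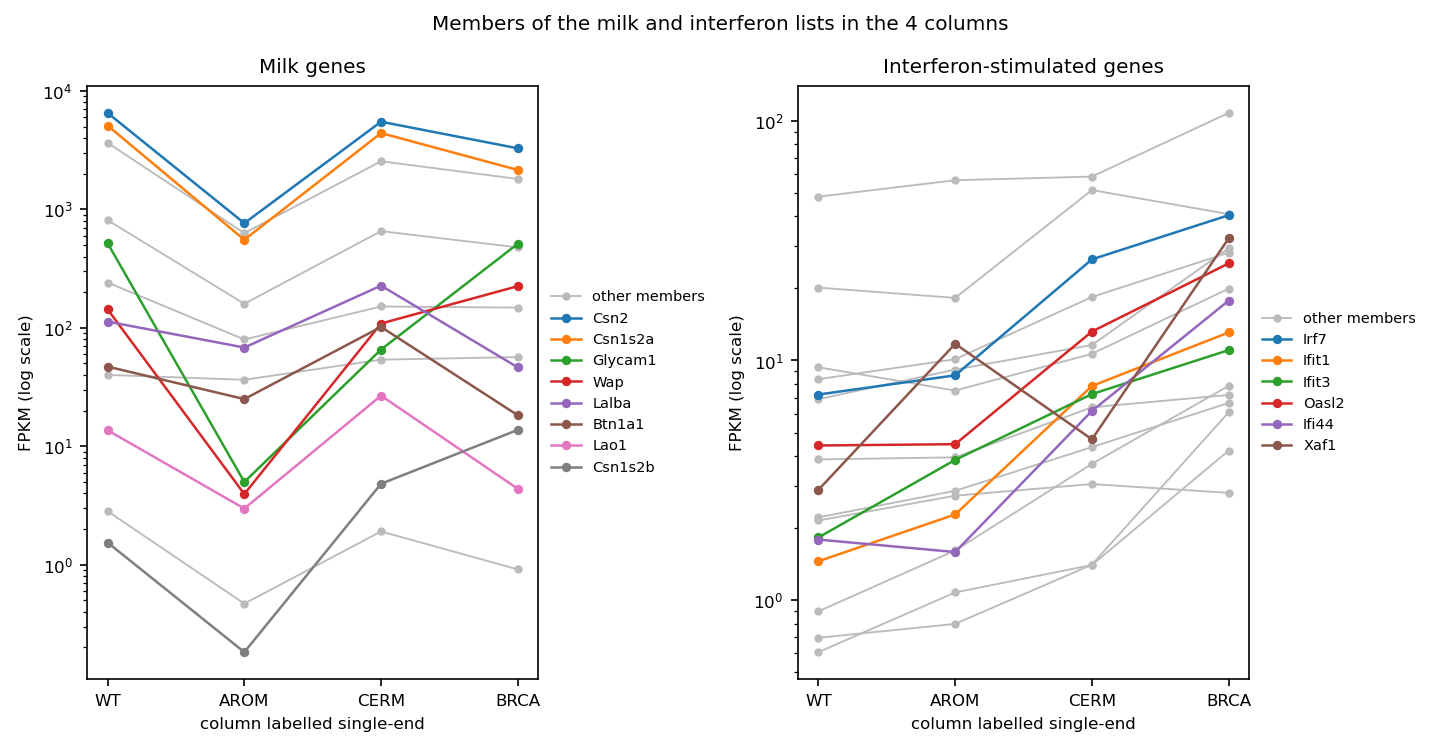
FPKM on a log axis of the 13 milk genes (left) and 17 interferon-stimulated genes (right) analysed, in the 4 columns labelled single-end (x axis); each line joins the values of 1 gene, and genes not named are grey. Csn2 stands at 764 FPKM in AROM against 6520.2 in WT, and Irf7 at 40.3 FPKM in the column labelled BRCA against 7.21 in WT.

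The comparison of CERM with WT asked the same of the Esr1 transgene. Interferon-stimulated genes were higher in CERM: 8 of 17 were at least 2-fold higher, none was 2-fold lower, and the median log2 fold change was 0.73. Ifit1, which encodes an antiviral RNA-binding protein, was at 7.83 FPKM against 1.45 in WT, Irf7, a transcription factor gene of the interferon response, at 26.4 FPKM against 7.21, and Ifit3 at 7.24 FPKM against 1.83. Cytotoxic lymphocyte genes had a median of 0.76, with 1 of 8, the granzyme gene Gzma, past 2-fold (8.59 FPKM against 3.41). MHC class II genes had a median of 0.58, with 1 of 6, H2-DMa, past 2-fold (32.0 FPKM against 14.9). Of the 5 mast cell genes 1 passed, the histidine decarboxylase gene Hdc (4.44 FPKM against 1.42), with a list median of 0.91. The neutrophil gene S100a9 was at 15.5 FPKM against 3.51. Immediate early genes had a median of 0.66 and 2 of 11 past 2-fold, Nr4a1 (49.4 FPKM against 7.73) and Dusp1 (42.3 FPKM against 19.6).

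Skeletal muscle genes were higher in CERM as well, 10 of 11 by 2-fold or more, with a median of 1.56; Actn3 was at 908 FPKM against 194 and Myh4 at 1692 FPKM against 387. Foxi1, a forkhead factor gene of ion-transporting epithelial cells, was at 26.3 FPKM against 1.30, and Cck, the cholecystokinin gene, at 31.0 FPKM against 2.85. Myoc was at 11.6 FPKM against 0.416, the chloride channel gene Clic6 at 18.9 FPKM against 2.01, the acute phase gene Saa1 at 24.0 FPKM against 3.46, and Inmt, a methyltransferase gene, at 35.3 FPKM against 5.74. The brown adipocyte genes Elovl3 (22.9 FPKM against 5.39) and Dio2 (4.91 FPKM against 1.55) were higher, 2 of 6 of that list.

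Lower in CERM were Glycam1 (65.5 FPKM against 518) and Madcam1 (2.36 FPKM against 10.2), both in the list of 3 lymph node stroma genes analysed. Glycam1 was the only one of 13 milk genes 2-fold lower, while Csn1s2b (4.82 FPKM against 1.54), Btn1a1 (102 FPKM against 47.0) and Lalba, the alpha-lactalbumin gene (227 FPKM against 113), were 2-fold higher. H2-Ea-ps, an MHC class II gene listed as a pseudogene, was at 3.68 FPKM against 58.4. Abhd1 was at 1.28 FPKM against 18.5, and the recombination factor genes Psmc3ip and Eme1 at 2.40 FPKM against 22.7 and 0.349 FPKM against 7.63. Lipogenesis genes had a median of -0.54, with Scd1, the stearoyl-CoA desaturase gene, past 2-fold (3323 FPKM against 7561). In the estrogen response list 1 of 11, Areg, which encodes the estrogen-induced growth factor amphiregulin, passed 2-fold (15.7 FPKM against 36.2), and the median was -0.47. Luminal epithelial genes had a median of -0.55, with none of 13 past 2-fold. Of the 24 proliferation genes Mcm6 was lower (9.56 FPKM against 20.5), with a list median of -0.48. The oxytocin receptor gene Oxtr (14.5 FPKM against 38.2) and Krt15 (3.03 FPKM against 7.598) were the 2 of 9 basal genes 2-fold lower.

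In all, 391 genes were at least 2-fold higher and 117 at least 2-fold lower in CERM than in WT. The interferon, muscle and immediate early medians stood above every one of 10000 random lists of matched expression (100th percentile), and the luminal epithelial, proliferation, estrogen response, lipogenesis and lymph node stroma medians below every one. The lymph node stroma median was -1.74, and 23 of the 24 proliferation genes lay below 0. Further distant values were those of Zbtb20 (134 FPKM against 9.23), the kinase genes Map3k15 (6.77 FPKM against 62.1) and Hipk3 (28.3 FPKM against 149), and the microRNA processing gene Dgcr8 (5.82 FPKM against 28.5). Medians of the macrophage and matrix lists, 0.10 and -0.04, were near 0, the second above 0 under median-ratio scaling. In the paired-end columns, whose values are not given here, these lists were higher and the muscle list was higher by less.

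**Figure D3:**
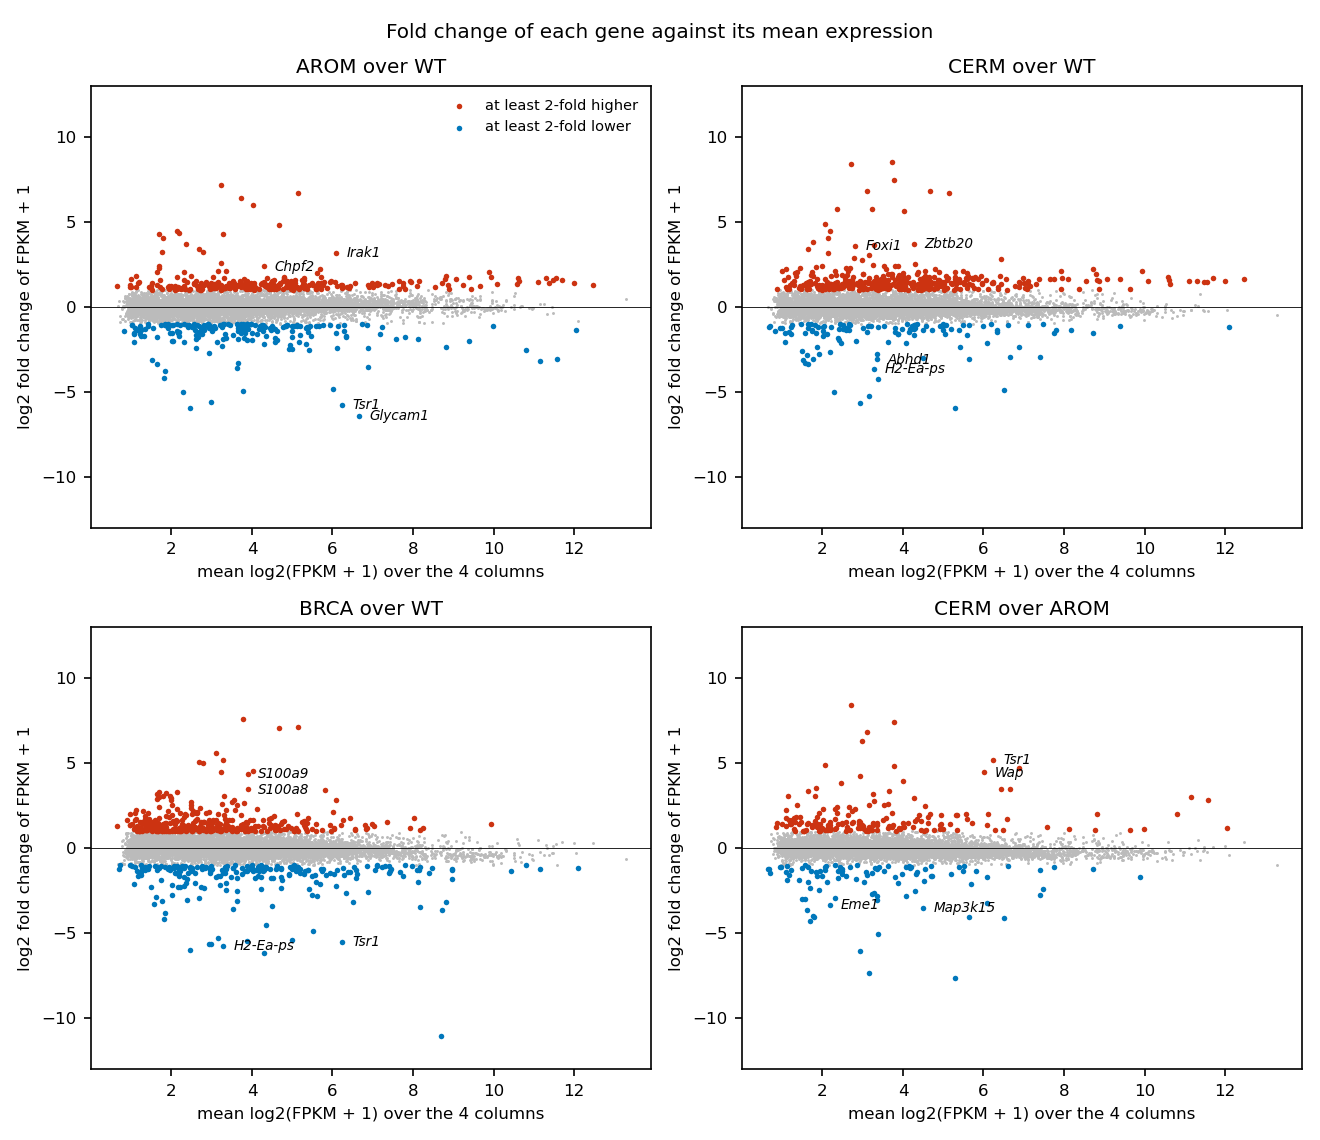
Log2 fold change on the FPKM + 1 scale (y axis) against mean log2(FPKM + 1) over the 4 columns (x axis) for each of the 11715 genes, in 4 comparisons. Genes at least 2-fold higher are red and those at least 2-fold lower are blue, and a few of the genes described are named. The column labelled BRCA over WT has 348 red and 227 blue points, and AROM over WT 280 and 199; the most extreme points include genes listed at 0 in a column.

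The column labelled BRCA was compared with WT to ask which genes differ in the Brca1 model. Members of several immune lists were higher, and so were most analysed members of the interferon, neutrophil, B cell and plasma cell lists. Of the genes listed, 5 of 11 neutrophil, 3 of 12 B cell and 4 of 8 plasma cell genes were analysed. Of the interferon-stimulated genes, 14 of 17 were at least 2-fold higher, with a median log2 fold change of 1.94: Xaf1 was at 32.3 FPKM against 2.89 in WT, Ifi44 at 17.8 FPKM against 1.79, Ifit1 at 13.1 FPKM against 1.45 and Irf7 at 40.3 FPKM against 7.21. Neutrophil genes were higher in 4 of 5, among them the calprotectin genes S100a9 (92.2 FPKM against 3.51) and S100a8 (75.3 FPKM against 5.91). All 3 B cell genes analysed were higher, with the B cell receptor gene Cd79a at 16.0 FPKM against 2.40, and so were 3 of 4 plasma cell genes, with Derl3 at 9.81 FPKM against 2.004. Macrophage genes were higher in 5 of 13, with the integrin gene Itgam at 7.83 FPKM against 2.22 and the complement gene C1qb at 157 FPKM against 73.1. MHC class II genes were higher in 3 of 6, with H2-Eb1 at 222 FPKM against 50.6. Chemokine and cytokine genes were higher in 7 of 18 and lower in 1. Ccl8, which encodes a monocyte chemoattractant, was at 351 FPKM against 31.3, and the interleukin gene Il1b at 5.73 FPKM against 0.783. The T cell list had 1 of 10 past 2-fold, the kinase gene Lck (8.70 FPKM against 3.39), and a median of 0.87. The cytotoxic list had 2 of 8 higher, with Ccl5 at 68.8 FPKM against 27.7, and the mast cell list 2 of 5, with Hdc at 6.31 FPKM against 1.42. Dendritic cell genes went both ways, with Siglech at 4.29 FPKM against 0.779 and Cd209a at 0.404 FPKM against 4.85. None of the 7 MHC class I presentation genes passed 2-fold, and their median of 0.02 was at 0 or below under median-ratio scaling. Of the 4 checkpoint and regulatory T cell genes 1, Ido1, was higher (3.28 FPKM against 0.0740). Of the 3 lymph node stroma genes, the chemokine gene Cxcl13 was higher (15.2 FPKM against 2.59) and Madcam1 lower (1.47 FPKM against 10.2).

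Other genes with high ratios were the interferon-inducible Gbp1 (23.4 FPKM against 1.42), the protease gene Ctse (13.7 FPKM against 0.726), the acute phase gene Saa3 (21.7 FPKM against 1.39) and Serpina1b, of a family of near-identical antitrypsin genes (8.81 FPKM against 0.272). Matrix genes were higher in 3 of 15, among them Fn1 (66.9 FPKM against 29.4) and Col3a1 (478 FPKM against 224). Of the 24 proliferation genes Top2a passed 2-fold (16.99 FPKM against 7.40), and the median was 0.37. Of the luminal epithelial genes 1 of 13, Cldn4, was higher (54.9 FPKM against 18.5), with a list median of 0.19, and of the luminal progenitor genes 1 of 6, Gabrp (11.2 FPKM against 5.04), with a median of 0.29. The casein gene Csn1s2b was at 13.7 FPKM against 1.54. Immediate early genes were higher in 3 of 11, with Atf3 at 16.6 FPKM against 4.46.

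Among hormone-responsive genes, 3 were lower in the column labelled BRCA. Tnfsf11 was at 1.15 FPKM against 15.4, Areg at 6.12 FPKM against 36.2, and Cited1, a coregulator gene of estrogen receptor, at 10.4 FPKM against 25.0. They made 3 of 8 hormone-sensing genes lower, while Prom1 was higher (6.44 FPKM against 2.26), and the median was -0.61. The same genes were the 3 of 11 estrogen response genes lower, and that list's median of -0.29 was above 0 after quantile normalization. Milk genes were lower in 6 of 13, with Lalba at 46.3 FPKM against 113 and Btn1a1 at 18.3 FPKM against 47.0, but Glycam1 stood at 512 FPKM against 518. Lipogenesis genes were lower in 7 of 10, with a median of -1.22: the elongase gene Elovl6 was at 46.7 FPKM against 143 and Acly, the ATP citrate lyase gene, at 185 FPKM against 498. Of the 12 white adipocyte genes 2 were lower, Retn, the resistin gene (96.7 FPKM against 858), and the adrenergic receptor gene Adrb3 (29.1 FPKM against 84.1). The fold change lay below 0 for 11 of the 12, with a median of -0.62. Brown adipocyte genes went the other way, with a median of 0.70 and 2 of 6 at least 2-fold higher, Elovl3 (12.9 FPKM against 5.39) and Dio2 (4.14 FPKM against 1.55). The endothelial junction gene Cldn5 was at 14.8 FPKM against 46.0, 1 of 11 endothelial genes past 2-fold. Low ratios also belonged to H2-Ea-ps (0.113 FPKM against 58.4), Gchfr, a regulator gene of tetrahydrobiopterin synthesis (1.16 FPKM against 48.8), and Rarres1 (0.813 FPKM against 20.2). Among 17 p53 target genes, Phlda3 was lower (51.5 FPKM against 152) and Pmaip1 higher (3.95 FPKM against 1.30), and the median was 0.09.

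In all, 348 genes were at least 2-fold higher and 227 at least 2-fold lower in the column labelled BRCA than in WT. The higher genes made up 60.5% of these, but 51.7% with a minimum of 5 FPKM. The interferon, plasma cell, macrophage, T cell, MHC class II, chemokine and matrix medians stood above every one of 10000 random lists of matched expression (100th percentile), and the lipogenesis, milk, hormone-sensing and white adipocyte medians below every one. The neutrophil median of 1.41 was 2.44 over the 4 of its genes kept by a minimum of 5 FPKM. Further low values were those of Tsr1 (11.9 FPKM against 592), Map3k15 (4.97 FPKM against 62.1) and Ercc2 (4.79 FPKM against 40.3).

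**Figure D4:**
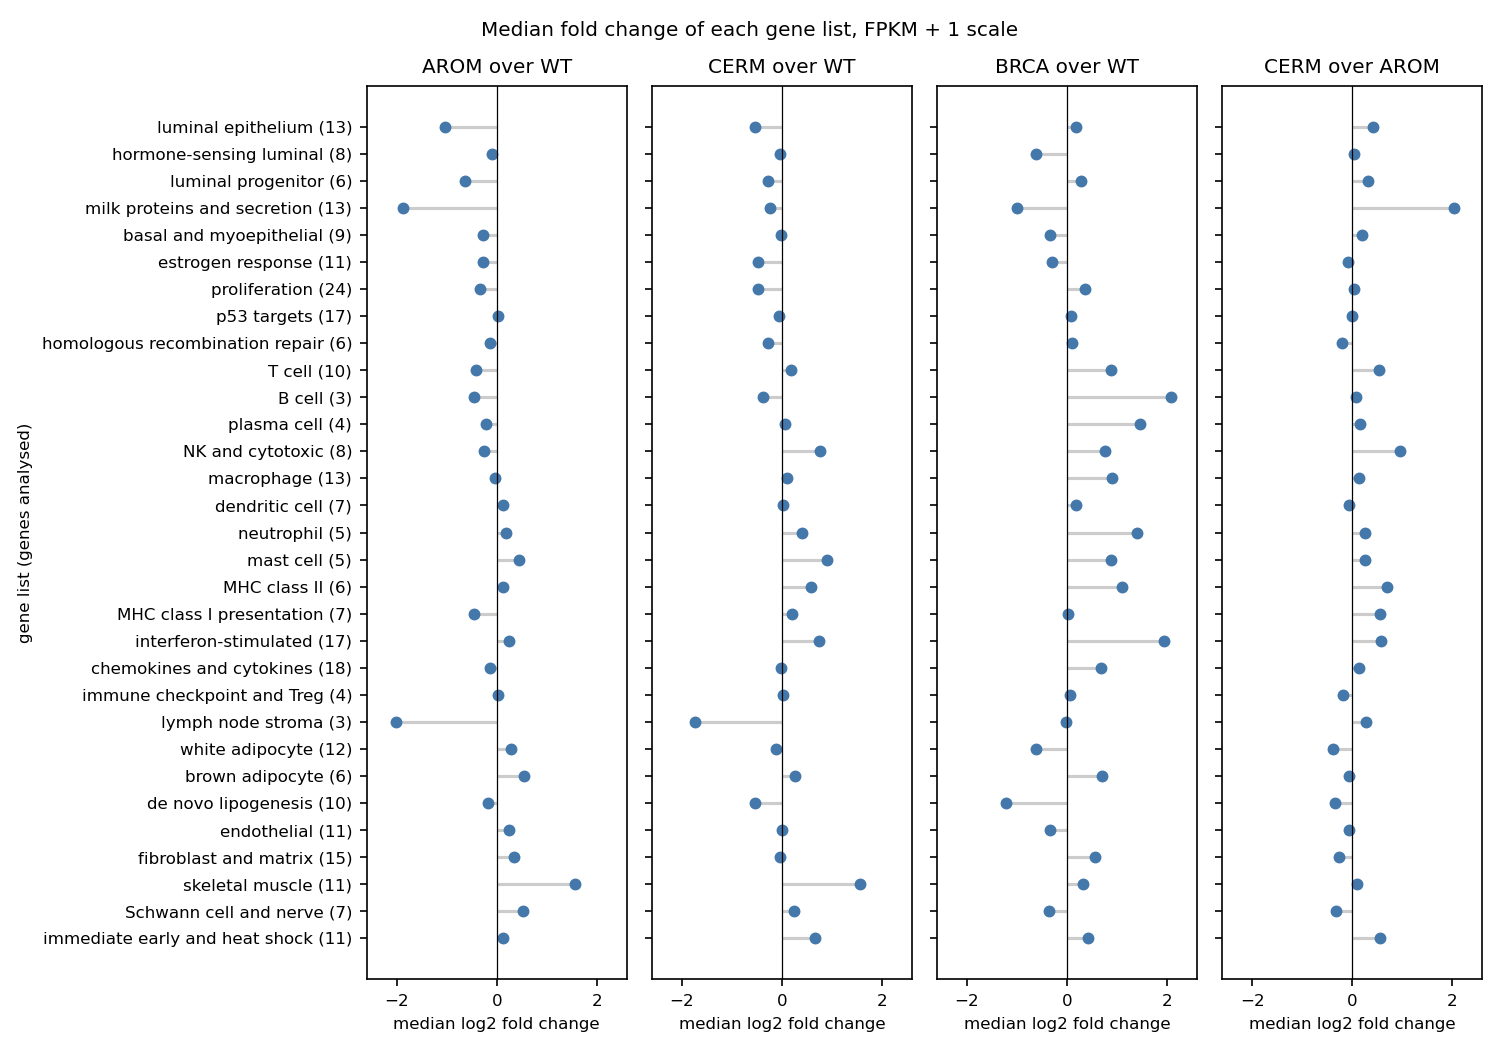
Median log2 fold change on the FPKM + 1 scale (x axis) of the 31 gene lists with at least 3 genes analysed (y axis, with the number of genes), in 4 comparisons of the columns labelled single-end; each point is the median of 1 list, joined to 0 by a line. The milk list lies at -1.88 in AROM over WT, and the interferon list at 1.94 in the column labelled BRCA over WT.

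CERM and AROM were then compared directly. Milk genes were higher in CERM, 10 of 13 by 2-fold or more, with a median of 2.03: Wap was at 109 FPKM against 3.95 in AROM, Glycam1 at 65.5 FPKM against 4.99, Csn1s2a at 4411 FPKM against 554 and Csn2 at 5499.7 FPKM against 764. Pigr was at 21.9 FPKM against 1.24, and the luminal progenitor gene Elf5 at 83.6 FPKM against 39.0. Luminal epithelial genes had a median of 0.41, with none of 13 past 2-fold. Cytotoxic lymphocyte genes were higher in 3 of 8, with the chemokine gene Xcl1 at 7.86 FPKM against 1.69, Gzma at 8.59 FPKM against 2.501 and Gzmb at 2.33 FPKM against 0.259. Interferon-stimulated genes were higher in 5 of 17 and lower in 1, with Irf7 at 26.4 FPKM against 8.67 and Ifi44 at 6.16 FPKM against 1.59, and the list median was 0.58. Immediate early genes were higher in 3 of 11, with Nr4a1 at 49.4 FPKM against 15.3 and Fos at 11.6 FPKM against 5.17. Of the 10 T cell genes Cd3g passed 2-fold (9.98 FPKM against 2.73), and of the 7 MHC class I presentation genes Tap1 (36.6 FPKM against 12.4).

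Ear11, which encodes an eosinophil-associated ribonuclease, was at 77.1 FPKM against 3.97, Saa1 at 24.0 FPKM against 1.72, and Trim12a, of a family of related genes, at 7.63 FPKM against 0.0139. Lower in CERM were Eme1 (0.349 FPKM against 12.4), Psmc3ip (2.40 FPKM against 23.1), Abhd1 (1.28 FPKM against 17.8), Prtn3 (0.892 FPKM against 13.1) and H2-Ea-ps (3.68 FPKM against 28.1). Oxtr was at 14.5 FPKM against 47.6 and Ido1 at 0.208 FPKM against 1.61. White adipocyte genes had a median of -0.39, with none of 12 past 2-fold. In all, 171 genes were at least 2-fold higher and 96 at least 2-fold lower in CERM than in AROM. Small RNA genes, with names such as Mir and Snor, made up 50 of these 267, against 101 of the 11715 genes analysed. Of the other distant values, Tsr1 was higher (404 FPKM against 9.80), and Map3k15 (6.77 FPKM against 88.3), Irak1 (22.3 FPKM against 217) and Dgcr8 (5.82 FPKM against 45.9) were lower.

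CERM was compared with the column labelled BRCA next, and several leukocyte lists were lower in CERM. B cell genes were lower in 3 of 3, with a median of -2.53, plasma cell genes in 3 of 4, neutrophil genes in 3 of 5 and macrophage genes in 3 of 13. Pglyrp1, a peptidoglycan recognition gene, was at 2.93 FPKM against 66.9 in the column labelled BRCA, Saa3 at 1.26 FPKM against 21.7, Ccl8 at 34.2 FPKM against 351, Glycam1 at 65.5 FPKM against 512 and the surfactant protein gene Sftpd at 2.59 FPKM against 26.6. Interferon-stimulated genes were lower in 5 of 17, with a median of -0.84, and proliferation genes in 7 of 24, with Birc5 at 5.99 FPKM against 20.4. Luminal epithelial genes were lower in 3 of 13, with Cldn4 at 12.4 FPKM against 54.9. Higher in CERM were Gchfr (23.6 FPKM against 1.16) and the receptor gene Mrgprg (18.8 FPKM against 1.17), as well as Tsr1 (404 FPKM against 11.9), Ercc2 (141 FPKM against 4.79) and Zbtb20 (134 FPKM against 5.09). Of 8 hormone-sensing genes 3 were higher in CERM, with Tnfsf11 at 7.28 FPKM against 1.15 and Areg at 15.7 FPKM against 6.12. Skeletal muscle genes were higher in 10 of 11, with a median of 1.24 that was 0.61 after quantile normalization. In all, 327 genes were at least 2-fold higher and 278 at least 2-fold lower in CERM than in the column labelled BRCA. The higher genes made up 54.1% of these, but 46.6% with a pseudocount of 0.1, 49.6% with 0.5, 45.0% at a threshold of 1.5-fold and 64.2% with a minimum of 5 FPKM.

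AROM and the column labelled BRCA were the furthest apart of the 6 comparisons, with 367 genes at least 2-fold higher and 548 at least 2-fold lower in AROM. The higher genes made up 40.1% of these, but 49.9% with a minimum of 5 FPKM. Interferon-stimulated genes were lower in AROM in 13 of 17, luminal epithelial genes in 9 of 13, milk genes in 7 of 13, T cell genes in 7 of 10 and proliferation genes in 8 of 24. Glycam1 was at 4.99 FPKM against 512 in the column labelled BRCA, Wap at 3.95 FPKM against 225, Sftpd at 0.649 FPKM against 26.6, Saa3 at 0.427 FPKM against 21.7, Ccl8 at 23.9 FPKM against 351 and S100a9 at 6.08 FPKM against 92.2. White adipocyte genes were higher in AROM in 5 of 12, with Retn at 957 FPKM against 96.7, and lipogenesis genes in 4 of 10, with Scd2 at 99.1 FPKM against 29.9. Skeletal muscle genes were higher in 8 of 11, with a median of 1.21 that was 0.61 after quantile normalization. Gchfr was at 64.9 FPKM against 1.16, Rarres1 at 33.1 FPKM against 0.813, H2-Ea-ps at 28.1 FPKM against 0.113, and the dendritic cell gene Cd209a at 10.4 FPKM against 0.404. Ercc2 (165 FPKM against 4.79) and Prmt2 (232 FPKM against 10.6) also stood high in AROM.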

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

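All tests in this part were chosen after the values were seen. Loci without a gene name enter no comparison of the report, and some of them had values in 1 genotype while listed at or near 0 in WT. A 0 can be a failed estimate, as for Ncl in WT, so these counts do not show absence. With FPKM of at least 1 in the column of a genotype and under 0.1 in WT, there were 44 such loci in AROM, 93 in CERM and 119 in the column labelled BRCA. The reverse, at least 1 in WT and under 0.1 in the column of the genotype, held for 28 unnamed loci in AROM, 60 in CERM and 83 in the column labelled BRCA. At FPKM of at least 1 in AROM and CERM and under 0.1 in WT and the column labelled BRCA there were 4 unnamed loci. Of these, XLOC_006497 was at 35.5 FPKM in AROM and 36.6 in CERM, XLOC_007602 at 6.30 and 13.6, and XLOC_023578 at 1.83 and 1.78, and all of these were listed at 0 in WT and the column labelled BRCA. XLOC_019271 was at 12.2 FPKM in AROM, 3.35 in CERM and 0.0385 in WT, and listed at 0 in the column labelled BRCA. AROM and CERM are the genotypes that carry the MMTV-rtTA transgene, per the labels. The files pair these loci with no name or position, and whether they hold transgene sequence was not tested.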

How the results depend on the processing

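The settings of other fold thresholds, loci and lists, a minimum in 1 column, and the omission of genes listed at 0 were chosen after seeing the data; pseudocounts, other filters and scalings were planned. Counts of genes past the threshold are given in the order AROM, CERM and the column labelled BRCA against WT, CERM against AROM, CERM against the column labelled BRCA, and AROM against the column labelled BRCA, and were 479, 508, 575, 267, 605 and 915 as reported. A threshold of 1.5-fold gave 1363, 1267, 1749, 863, 1841 and 2932, and a threshold of 4-fold 63, 78, 106, 73, 95 and 114. A pseudocount of 0.1 gave 732 for AROM against WT, 414 for CERM against AROM, 944 for CERM and 1378 for AROM against the column labelled BRCA. A minimum of 5 FPKM, which leaves fewer genes, gave 381 for the column labelled BRCA against WT. The other 61 of the 78 counts under an alternative lay within 1.5 times the reported count, those of both scalings included. Among them were the counts without small RNA genes, 436, 452, 521, 217, 558 and 860. Taken apart, 15 of the 78 counts of higher genes and 19 of the 78 counts of lower genes lay beyond 1.5 times. No named gene or list median past 2-fold turned its sign under an alternative that gave it a value. Of the fold changes of the genes ranked highest and lowest and of Esr1, Brca1, Trp53 and Pgr, 35 of 1049 moved by more than 1.5-fold, all under a smaller pseudocount. Of the list medians, 23 of 1782 did. A filter leaves a single gene's fold change as it was, so many of the 1049 could not move. A pseudocount cannot turn a gene's sign either, so for single genes only the scalings tested the sign. No paired analysis was possible because the columns are pooled and carry no replicate numbers. That limit holds for pairing by replicate number only. Matching the columns by read layout was possible from the deposited values, but it was set aside with the paired-end columns. Because the columns are pooled, the planned limma fits were not run, nor their replicate block, same-number correlation and averaging, layout term, library weights, fits of 2 genotypes, p-based threshold, leaving out of each library, and camera and fry list tests. The planned setting of the paired-end libraries alone was looked at before the columns were chosen, and its values are not given because 1 column per genotype was used; that of the single-end libraries alone became the columns labelled single-end, of which the WT column may hold the paired-end library too (this was not settled). Depth is unknown, so how much of a low gene's ratio is counting error could not be given.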

Other observations

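All tests of explanations in this part were chosen, or run again on the columns labelled single-end, after results had been seen. Genes of tissues around the gland were abundant in every column. Ckm, the muscle creatine kinase gene, was at 1766 FPKM in WT, 5292 in AROM, 5689 in CERM and 2287 in the column labelled BRCA. Ucp1, the brown fat uncoupling protein gene, was at 341 FPKM in WT, 421 in AROM, 349 in CERM and 485 in the column labelled BRCA. The 7 Schwann cell and nerve genes had a median log2 fold change of 1.06 in AROM against the column labelled BRCA, where 4 of them were at least 2-fold higher. Of the keratinocyte list 2 genes were analysed, and Krtdap was at 9.04 FPKM in WT, 11.7 in AROM, 3.14 in CERM and 1.40 in the column labelled BRCA. Of the erythrocyte list Alas2 alone was analysed, at 10.8 FPKM in WT, 6.96 in AROM, 19.5 in CERM and 16.3 in the column labelled BRCA. The T cell gene Cd4 was at 3.08 FPKM in WT, 1.05 in AROM, 0.989 in CERM and 6.21 in the column labelled BRCA.

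The milk genes were lower in AROM than in WT, with a list median of -1.88. The values argue against the scaling of the AROM column, since the median of all genes as deposited was -0.00048. A factor on a whole column moves the milk list and all genes nearly alike. Both other scalings, under which the milk median also lay below that of all genes (nearest value -1.813), therefore add little. A lower share of epithelium may account for part of it, since the luminal epithelium genes were lower too; the milk median lay -0.8403 from theirs, more than the luminal SD of 0.404 but less than the milk SD of 1.764, so the test did not decide. The basal and hormone-sensing lists, at -0.28 and -0.09, were lower by less, but smooth muscle also expresses several basal genes. The effect of the transgene itself remains open and untested.

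The interferon-stimulated genes were higher in the column labelled BRCA than in WT. A variant at 1 locus acting on neighbouring genes is argued against as a shared cause of the 14 genes past 2-fold. Of these, 9 had no other such gene within 10 genes. The list was chosen by pathway and not by position, so this count largely follows from where its members lie. It does not decide the cause for any single gene. More leukocytes in the tissue could account for it: the interferon median lay -0.1364 from the highest leukocyte list median. That comparison was lenient, since the highest list held the 3 B cell genes analysed, and the macrophage median of 0.91 lay below the interferon median of 1.94. The genotype, the colony of the mice and a variant in a regulator of scattered genes stay open and were not tested.

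A set of 106 genes was at least 4-fold apart between the column labelled BRCA and WT, some nearly all or none: H2-Ea-ps was at 0.113 FPKM against 58.4 and Gchfr at 1.16 FPKM against 48.8. Flanking DNA carried with the modified alleles would place such genes near Brca1 and Trp53. Within 50 genes of them lay 2 of 106 (Psmc3ip and Snord49a), the median of 10000 random gene sets. For the set as a whole this argues against an excess inside that window only, and it leaves those genes open. Flanking DNA reaching past 50 genes was not tested, so flanking DNA stays open. Different alleles at the H2 region could also set genes near it apart. Within 50 genes of H2-Ab1 lay 3 of 106 (H2-Ea-ps, H2-Eb1 and Gm11127), against a random median of 1 and a 93.6th percentile. H2-Ea-ps was low in CERM too, at 3.68 FPKM, with 28.1 FPKM in AROM. Different H2 alleles stay open. The labels give 1 strain, C57Bl/6, for all mice, and a strain difference was not tested otherwise.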
